A study of Homo sapiens with 6 samples.

How the data were processed

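Total RNA of 6 samples of WA09, an established human embryonic stem cell line, was measured on Affymetrix expression arrays, with 1 array per sample. The samples form 3 groups of 2 arrays: undifferentiated cells (hESC), nascent mesoderm cells positive for ISL1 (INM, day 4) and smooth muscle cells (SMC, day 21). Per the labels' protocols, both derivatives were made in defined medium with Wnt3a at 25 ng/ml and BMP4 at 50 ng/ml. Groups and replicate numbers were taken from the sample titles. Nothing in the labels states that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

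The deposited table holds log2 expression values for 33297 probe sets, and RMA and limma are the tools named in the submitters' processing notes, without versions. The log2 scale was read from the values themselves, which ran from 1.36 to 14.1 over the 6 arrays. The RMA settings, the array's genome build and any centring are not given in the sources used here. Array medians were 6.68 and 6.66 in hESC, 6.50 and 6.46 in INM, and 6.53 and 6.54 in SMC. Scanner files were not used here. No column of another sample was present.

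Probe sets were named through the platform's annotation table. Of the 33297 probe sets, 19460 carried 1 gene symbol, 1754 carried several and 12083 were unnamed here. Symbols were updated through the Entrez identifier to a reference gene table of assembly GRCh38.p14, which was used for names and gene classes only. The identifier matched for 19429 probe sets, and 31 symbols were kept as in the platform's table. Probe sets with several symbols named no gene. For the 769 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was kept and 1043 others were left out, which gave 18417 genes. Different probe sets of a gene were called in opposite directions for 12 genes in INM versus hESC, 1 in SMC versus INM and 5 in SMC versus hESC.

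The deposited values were used without further normalization and without a filter on low signal. A model of 3 group means was fitted to all 6 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 3 residual and 3.56 prior degrees of freedom, so that the groups shared 1 estimate of the spread. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 18417 genes, and a gene was called at an adjusted p under 0.05. Changes are differences of group means on the log2 scale with their standard error (SE). A moderated F test asked which genes differed between any of the groups. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333. The number of arrays limits the precision of every value.

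Gene lists for 34 cell types, pathways and complexes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. Each list's called members were counted over all genes and again, as rises and falls, with p-values adjusted over the list alone. With the correlation estimated for each list, camera called 0 lists in each of the 3 comparisons (8, 9 and 7 lists had an unadjusted p under 0.05), and fry, which tests whether a list's genes move on balance in 1 direction, called 17, 14 and 18 lists. The adjusted p with an estimated correlation stands beside each camera call made on all 6 arrays. That p-value also rests on only 3 residual degrees of freedom, so it is larger even where the estimated correlation lies below the preset value. Several genes belong to more than 1 list. Members without a probe set of their own were not measured, among them POU5F1 and NANOG, which lie only on probe sets with several symbols.

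Named genes followed a rule. It takes, per comparison, the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, leaving out genes without a symbol of their own, XIST and Y-linked genes. It adds 18 fixed marker genes where measured, and up to 4 members of each list with the largest change, together with members behind a count of 5 or fewer. The groups, the comparisons, the tests, the lists, the named-gene rule and the alternatives other than those named last were chosen before the data were examined.

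Comparisons that share arrays share their chance values. Overlaps and correlations were therefore set beside 20 simulations of unchanged groups and beside the overlap of independent lists. The group of 2 shared arrays leaves 1 array per part when divided, so the shared arrays were not split for the counts. A different INM array in each step was used only as a check on turning genes, added after the data were seen.

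In simulated data for the 18417 genes, 200 genes were changed in INM versus hESC. The fit recovered 4.48%, 88.1% and 100% of those changed by 0.5, 1 and 2 on the log2 scale. Of 135 calls, 7 were unchanged genes. The larger INM spread was not simulated. On 31 simulated lists of 20 uncorrelated genes camera called the list shifted by 0.5 and 0 of the unshifted lists.

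Alternatives were leaving out each array in turn, the replicate number as a block, a filter below the 30th percentile of signal, quantile normalization again, median centring, a variance trend with robust fitting, array weights, the mean of all probe sets of a gene, all probe sets singly, only the arrays compared, a minimum of 2-fold, and a test against a log2 change of 0.58 (treat). With an array left out, the group's lone array was assumed to vary like the other groups. Where leaving out an array ended the call of a named gene, the array named is the one with the highest adjusted p. Crossed replicate numbers and protein-coding genes alone were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.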

Results

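The series profiled gene expression in WA09 human embryonic stem cells and in 2 derivatives of the same line, and its title places the profiles beside a study of nucleosome positioning during differentiation. Undifferentiated cells (hESC), ISL1-positive nascent mesoderm after 4 days of Wnt3a and BMP4 (INM) and smooth muscle cells after 21 days (SMC) were each measured on 2 arrays, and 18417 genes were tested. The INM arrays stood further apart than the arrays of the other groups. Their correlation across genes was 0.985, against 0.991 in hESC and 0.993 in SMC, where genes are not independent replicates. The INM pair differed by more than 1 on the log2 scale in 700 genes, the hESC pair in 16 and the SMC pair in 11. The pooled replicate SD was 0.313 in INM, 0.149 in hESC and 0.132 in SMC. The sources used here give no measure of signal over background. Folds are therefore ratios of RMA signals, and only log2 changes of the signal are given for single genes where a group mean lay under 5.04, the lowest array median of unnamed probe sets, a limit chosen after the data were seen. The level of such a gene in that group is not shown to lie above background.

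**Figure D1:**
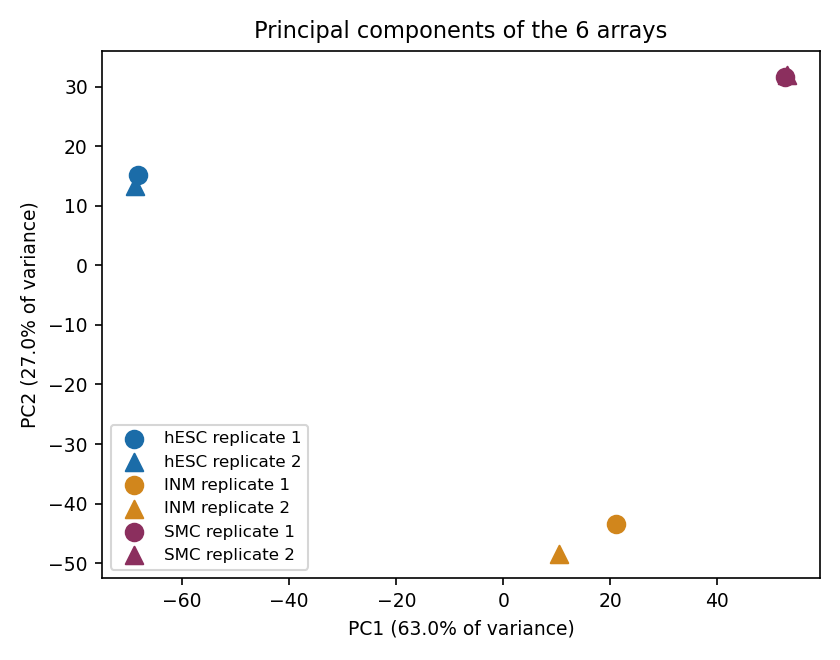
Principal components of the 6 arrays, from log2 values of 18417 genes, with colour for the group and shape for the replicate number. The first component (63.0% of variance) ran from hESC at -68.2 and -68.8 to SMC at 52.6 and 53, and the second (27.0%) set INM, at -43.5 and -48.4, apart from both.

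The comparison of INM with hESC asks what changed over the first 4 days. SOX2, a transcription factor of the pluripotent state (probe set 8084165), stood at 11.45 ± 0.02 in hESC and 5.72 ± 0.13 in INM (SD, n = 2), a 53.1-fold fall with a log2 change of -5.73 (SE 0.12, adjusted p = 6.1e-06). IDO1, an enzyme of tryptophan breakdown, fell, at -5.98 (SE 0.14) on the log2 scale, and CRIPTO, a co-receptor of NODAL, fell by 56.9-fold. HAND1, a transcription factor of early mesoderm and heart (probe set 8115391), rose 77.2-fold from 6.10 ± 0.01 to 12.37 ± 0.06 (SD, n = 2), with a log2 change of 6.27 (SE 0.12, adjusted p = 5.2e-06). ISL1, the marker by which INM is named, rose 17.1-fold, with a log2 change of 4.10 (SE 0.13, adjusted p = 1.7e-05). The largest rise by the named-gene rule was that of LUM, a proteoglycan of collagen matrix (probe set 7965403), from 3.63 ± 0.03 to 11.46 ± 0.11 (SD, n = 2), a log2 change of 7.83 (SE 0.12, adjusted p = 3.1e-06).

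Further large rises were those of HAPLN1, a link protein of hyaluronan matrix (6.28, SE 0.19), DKK1, a secreted Wnt antagonist (5.93, SE 0.53), LIX1 (5.83, SE 0.13), the homeobox gene MSX2 (5.82, SE 0.14), the hypoxia-inducible factor gene EPAS1 (5.71, SE 0.11) and WLS, a carrier of secreted Wnt proteins (5.56, SE 0.11). Further large falls were those of the deubiquitinase gene USP44 (-5.25, SE 0.16), GRPR (-4.50, SE 0.11), VWDE (-4.16, SE 0.15), PWAR6 (-4.01, SE 0.30) and CRIPTO3 (-4.15, SE 0.23), a near-identical copy of CRIPTO whose own level is uncertain. The early mesoderm genes TBXT and EOMES were not called at day 4, at -0.04 (SE 0.12, adjusted p = 0.821) and 0.29 (SE 0.14, adjusted p = 0.168). CDH1, the epithelial cadherin, was not called either, at -0.36 (SE 0.38, adjusted p = 0.494), and stood at 10.63 ± 0.92 in INM (SD, n = 2). KDR, a receptor of vascular growth factor, had INM arrays at 9.09 and 11.47 and a change of -0.01 (SE 0.67, adjusted p = 0.995), and it was called higher without INM replicate 1, at 1.18, and lower without INM replicate 2, at -1.196. MYH11, the smooth muscle myosin heavy chain, was not called, at 0.13 (SE 0.14, adjusted p = 0.518). VIM rose by 1.56 (SE 0.22).

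In the pluripotency list 0 of 21 measured genes rose, 13 fell and 8 did neither (0 and 17 adjusted over the list alone). Examples were PRDM14 at -3.72 and ZSCAN10 at -2.82. The pluripotency list had a median change of -1.92 (camera adjusted p = 1.3e-08, adjusted p = 0.175 with an estimated correlation). The lateral and cardiac mesoderm genes went up: 15 of 24 measured genes rose, 1 fell (FOXH1) and 8 did neither (15 and 1 adjusted over the list alone). Examples were TBX20 at 4.19, PRRX1 at 4.64 and TBX3 at 4.13. The lateral mesoderm list had a median change of 1.77 (camera adjusted p = 1.1e-06, adjusted p = 0.389 with an estimated correlation). Of the genes of mesenchymal transition, 11 of 16 measured genes rose, 1 fell (THY1) and 4 did neither (11 and 1 adjusted over the list alone). Examples were the repressor SNAI2 at 5.48, ZEB2 at 4.79 and the mesenchymal cadherin CDH11 at 4.10. The mesenchymal transition list had a median change of 2.38 (camera adjusted p = 2.9e-06, adjusted p = 0.394 with an estimated correlation). For extracellular matrix genes, 20 of 28 measured genes rose, 0 fell and 8 did neither (21 and 0 adjusted over the list alone). Examples were COL6A3 at 4.44 and tenascin (TNC) at 3.88. The matrix list had a median change of 2.00 (camera adjusted p = 2.7e-10, adjusted p = 0.175 with an estimated correlation). Among epicardial and fibroblast markers 10 of 15 measured genes rose, 2 fell (PDPN and THY1) and 3 did neither (10 and 2 adjusted over the list alone). An example was the growth factor receptor PDGFRB at 2.46. The epicardial and fibroblast list had a median change of 1.36 (camera adjusted p = 0.00115, adjusted p = 0.180 with an estimated correlation). The fixed mesoderm markers GATA4 and PDGFRA rose by 2.03 (SE 0.45) and 1.87 (SE 0.42). In the INM pair, replicate 1 minus replicate 2 had a median of -0.54 over the mesoderm list and 0.34 over the matrix list. Without INM replicate 2 the change of GATA4 was 1.23, that of PDGFRA 1.14 and the mesoderm list median 0.96. Calls were kept in all 6 fits with 1 array left out for 11 of 13 pluripotency falls, 9 of 15 lateral mesoderm rises, 19 of 20 matrix rises and 5 of 10 epicardial rises. Some calls ended when 1 array was left out: without hESC replicate 1 the adjusted p was 0.122 for PDPN and 0.0945 for GATA4, and without hESC replicate 2 it was 0.0975 for PDGFRA.

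Both smooth muscle lists were called higher already at day 4. ACTA2, smooth muscle alpha-actin (probe set 7934906), rose 31.7-fold from 6.42 ± 0.02 to 11.41 ± 0.79 (SD, n = 2), with a log2 change of 4.99 (SE 0.33, adjusted p = 1.8e-04), and calponin (CNN1) rose by 1.48 (SE 0.16). In the contractile list 14 of 21 measured genes rose, 1 fell (ACTG2) and 6 did neither (14 and 3 adjusted over the list alone). The contractile list had a median change of 0.67 (camera adjusted p = 8.5e-04, adjusted p = 0.199 with an estimated correlation). Replicate 1 minus replicate 2 of INM had a median of 0.18 over this list. Among its regulators 8 of 15 measured genes rose, 0 fell and 7 did neither (9 and 0 adjusted over the list alone). An example was the coactivator MYOCD at 2.85 (SE 0.24). The smooth muscle regulator list had a median change of 0.78 (camera adjusted p = 3.8e-04, adjusted p = 0.175 with an estimated correlation). TAGLN was not called, at 0.67 (SE 0.33, adjusted p = 0.170), and stood at 9.76 ± 0.80 in INM (SD, n = 2). In all 6 fits with 1 array left out, calls were kept for 4 of 14 contractile rises and 2 of 8 regulator rises. The call of ACTG2 ended without hESC replicate 2, where its change was -1.27.

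The target lists of both supplied signals were called higher. In the BMP list 14 of 16 measured genes rose, 0 fell and 2 did neither (14 and 0 adjusted over the list alone). Examples were DLX5 at 5.03, GATA3 at 3.92 and the BMP antagonist NOG at 4.08. The BMP target list had a median change of 2.30 (camera adjusted p = 1.8e-10, adjusted p = 0.175 with an estimated correlation). Among Wnt targets 8 of 14 measured genes rose, 0 fell and 6 did neither (9 and 0 adjusted over the list alone). Examples were LEF1 at 5.24 and APCDD1 at 2.86. The Wnt target list had a median change of 1.22 (camera adjusted p = 2.5e-04, adjusted p = 0.175 with an estimated correlation). For YAP targets 7 of 13 measured genes rose, 0 fell and 6 did neither (7 and 0 adjusted over the list alone). Examples were ANKRD1 at 5.24 and TGFB2 at 4.34. The YAP target list had a median change of 0.91 (camera adjusted p = 1.3e-04, adjusted p = 0.412 with an estimated correlation); INM replicate 1 was the higher in 11 of the 13 genes, with a median difference of 0.75, and without it the list median was 0.49. Among trophoblast and amnion markers 7 of 18 measured genes rose, 0 fell and 11 did neither (8 and 0 adjusted over the list alone). Examples were TFAP2A at 5.37 and GATA3, which is also a BMP target. The trophoblast and amnion list had a median change of 0.60 (camera adjusted p = 0.00399, adjusted p = 0.412 with an estimated correlation). Among neural crest markers 7 of 11 measured genes rose, 0 fell and 4 did neither (7 and 0 adjusted over the list alone). Examples were MSX2 at 5.82 and SNAI2 at 5.48. The neural crest list had a median change of 0.60 (camera adjusted p = 2.5e-04, adjusted p = 0.180 with an estimated correlation). In the HOX list 9 of 27 measured genes rose, 1 fell (HOXB1) and 17 did neither (9 and 1 adjusted over the list alone). Examples were HOXB2 at 2.58 and HOXD10 at 1.94. The HOX list had a median change of 0.34 (camera adjusted p = 0.0137, adjusted p = 0.617 with an estimated correlation), a call that was lost without hESC replicate 2 (adjusted p = 0.0795). The calls kept with any 1 array left out were those of 12 of 14 BMP rises, 6 of 8 Wnt rises, 5 of 7 YAP rises and 4 of 7 trophoblast rises. The same held for 4 of 7 neural crest rises and 3 of 9 HOX rises. The call of HOXB1 ended without hESC replicate 1, at -0.31.

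Replication-dependent histone genes were called lower in INM as a list. Of these, 1 of 57 measured genes rose (H2BC12), 24 fell and 32 did neither (1 and 26 adjusted over the list alone). Examples were H1-1 at -2.50 (SE 0.16) and H2BC14 at -2.10 (SE 0.18). The histone list had a median change of -0.50 (camera adjusted p = 1.1e-06, adjusted p = 0.617 with an estimated correlation). Unnamed probe sets and small nucleolar RNA genes moved the same way, with median changes of -0.30 over 12083 probe sets and -0.76 over 175 genes. Among histone chaperones 0 of 22 measured genes rose, 5 fell (NAP1L2, NAP1L3, NASP, NPM1 and NPM3) and 17 did neither (0 and 5 adjusted over the list alone). The chaperone list had a median change of -0.28 (camera adjusted p = 0.0405, adjusted p = 0.744 with an estimated correlation), and the call was lost without hESC replicate 2 (adjusted p = 0.113) or INM replicate 1 (adjusted p = 0.407). Chromatin remodelling genes had no list call, and 14 of 49 measured genes rose, 4 fell (BPTF, CHD6, INO80 and RUVBL1) and 31 did neither (15 and 4 adjusted over the list alone), with the helicase gene CHD3 at 1.18 (SE 0.17); the list was called higher without hESC replicate 2 (adjusted p = 0.0324) or INM replicate 1 (adjusted p = 0.0227). Polycomb and DNA methylation genes had no list call: 3 of 19 measured genes rose (PCGF6, PHC2 and TET2), 7 fell and 9 did neither (3 and 7 adjusted over the list alone), with the DNA methyltransferase DNMT3B at -2.62 (SE 0.17), PHC1 at -2.13 (SE 0.14) and the demethylating enzyme TET2 at 1.86 (SE 0.13); the list median of -0.16 became 0.03 with median centring. In the histone variant list 2 of 8 measured genes rose (MACROH2A1 and MACROH2A2), 1 fell (H2AZ1) and 5 did neither (2 and 1 adjusted over the list alone), with MACROH2A2 at 2.57 (SE 0.17). Without INM replicates 1 and 2 the histone median was -0.26 and -0.76, and the chaperone median -0.13 and -0.50. Calls were kept in all 6 fits with 1 array left out for 9 of 24 histone falls, 4 of 14 remodelling rises and 3 of 7 polycomb falls. Calls of these genes ended in fits with fewer arrays: without hESC replicate 1 the adjusted p was 0.0765 for H2BC12, 0.0905 for NASP and 0.197 for PCGF6, and without hESC replicate 2 it lay between 0.0570 and 0.191 for NAP1L2, NPM1, NPM3, CHD6, INO80, RUVBL1, PHC2 and H2AZ1.

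Cell division genes were not called as lists. In the DNA replication list 2 of 24 measured genes rose (CCNE2 and POLE), 0 fell and 22 did neither (0 and 0 adjusted over the list alone). In the mitosis list 0 of 20 measured genes rose, 1 fell (BUB1B) and 19 did neither (0 and 0 adjusted over the list alone). The medians of these lists were -0.21 and -0.26. INM replicate 2 was the higher in 24 of 24 and 20 of 20 of these genes, with median differences of -0.78 and -1.14. Without INM replicate 2 both lists were called lower, at -0.59 (adjusted p = 7.8e-05) and -0.96 (adjusted p = 1.7e-07). The single-gene calls ended too without hESC replicate 1, at 0.52 for CCNE2, 0.42 for POLE and -1.14 for BUB1B.

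The remaining lists were not called, with camera adjusted p between 0.105 and 0.969. In the epithelial list 4 of 19 measured genes rose (CLDN4, KRT18, KRT19 and KRT8), 5 fell (CLDN3, CLDN6, CLDN7, ST14 and TJP3) and 10 did neither (4 and 6 adjusted over the list alone). In the primitive streak list 2 of 18 measured genes rose (EVX1 and MIXL1), 2 fell (MESP1 and NODAL) and 14 did neither (2 and 2 adjusted over the list alone). In the paraxial and intermediate mesoderm list 1 of 17 measured genes rose (PAX3), 3 fell (DLL3, HOXB1 and MEOX2) and 13 did neither (0 and 0 adjusted over the list alone). In the endoderm list 2 of 14 measured genes rose (APOA2 and CXCR4), 1 fell (FOXA3) and 11 did neither (2 and 0 adjusted over the list alone). Among neuroectoderm markers 2 of 16 measured genes rose (MAP2 and NES), 1 fell (OTX2) and 13 did neither (2 and 1 adjusted over the list alone), with OTX2 at -3.39 (SE 0.30). For endothelial markers 2 of 16 measured genes rose (ENG and ERG), 0 fell and 14 did neither (1 and 0 adjusted over the list alone). For haematopoietic markers 3 of 13 measured genes rose (CSF1R, HBZ and RUNX1), 0 fell and 10 did neither (3 and 0 adjusted over the list alone). For cardiomyocyte markers 1 of 14 measured genes rose (MYL7), 2 fell (TNNI3 and TTN) and 11 did neither (1 and 1 adjusted over the list alone). For skeletal muscle markers 1 of 12 measured genes rose (DMD), 1 fell (MYH2) and 10 did neither (0 and 0 adjusted over the list alone). In the glycolysis list 4 of 16 measured genes rose (PFKL, PFKM, PFKP and SLC2A3), 2 fell (ALDOC and HK2) and 10 did neither (4 and 2 adjusted over the list alone). In the oxidative phosphorylation list 8 of 75 measured genes rose, 12 fell and 55 did neither (5 and 10 adjusted over the list alone). In the MHC class I list 1 of 7 measured genes rose (B2M), 3 fell (PSMB8, TAP1 and TAP2) and 3 did neither (1 and 4 adjusted over the list alone). In the p53 target list 2 of 12 measured genes rose (SESN2 and ZMAT3), 1 fell (RRM2B) and 9 did neither (2 and 1 adjusted over the list alone). In the ribosomal protein list 3 of 62 measured genes rose (RPL26L1, RPL29 and RPS23), 11 fell and 48 did neither (3 and 9 adjusted over the list alone). Ribosomal protein genes were called lower without hESC replicate 1 (adjusted p = 0.0394) or with the low-signal filter (adjusted p = 0.0211). The median changed sign under another scaling for the primitive streak, paraxial mesoderm, endoderm, haematopoietic, skeletal muscle, oxidative phosphorylation and ribosomal lists. Median and mean had opposite signs for the primitive streak (-0.07 and 0.01), endoderm (-0.01 and 0.03), haematopoietic (-0.05 and 0.11) and cardiomyocyte (0.04 and -0.02) lists. In all 6 fits with 1 array left out, calls were kept for 1 of 8 oxidative phosphorylation rises, 3 of 12 oxidative phosphorylation falls and 2 of 11 ribosomal falls. Calls of these members ended: without hESC replicate 1 the adjusted p lay between 0.0566 and 0.222 for CLDN6, TJP3, EVX1, MIXL1, MESP1, HOXB1, MEOX2, FOXA3, NES, ENG, ERG, RUNX1, TNNI3, MYH2, SLC2A3, ALDOC, ZMAT3, RPL29 and RPS23, and without hESC replicate 2 it lay between 0.0514 and 0.183 for CLDN4, NODAL, PAX3, DLL3, CSF1R, HBZ, DMD, PFKM, PSMB8 and RPL26L1.

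Over all genes 6217 of 18417 (33.8%) were called between INM and hESC, of which 3486 were higher and 2731 lower. At least 2-fold changes numbered 1322 up and 741 down, and at least 8-fold changes 126 and 36. The 2 groups did not overlap in 68.2% of genes, where chance gives 33.3%. The share of calls that were higher was 56.1%, against 66.1% with quantile normalization again and 76.2% with median centring, which moved the all-gene median by 0.15 and 0.19. Without hESC replicate 1 there were 2939 calls and without hESC replicate 2 there were 3327. With all 33297 probe sets tested singly 10688 were called, of which 4010 were higher and 6678 lower. The arrays compared, fitted alone, gave 4498 calls.

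**Figure D2:**
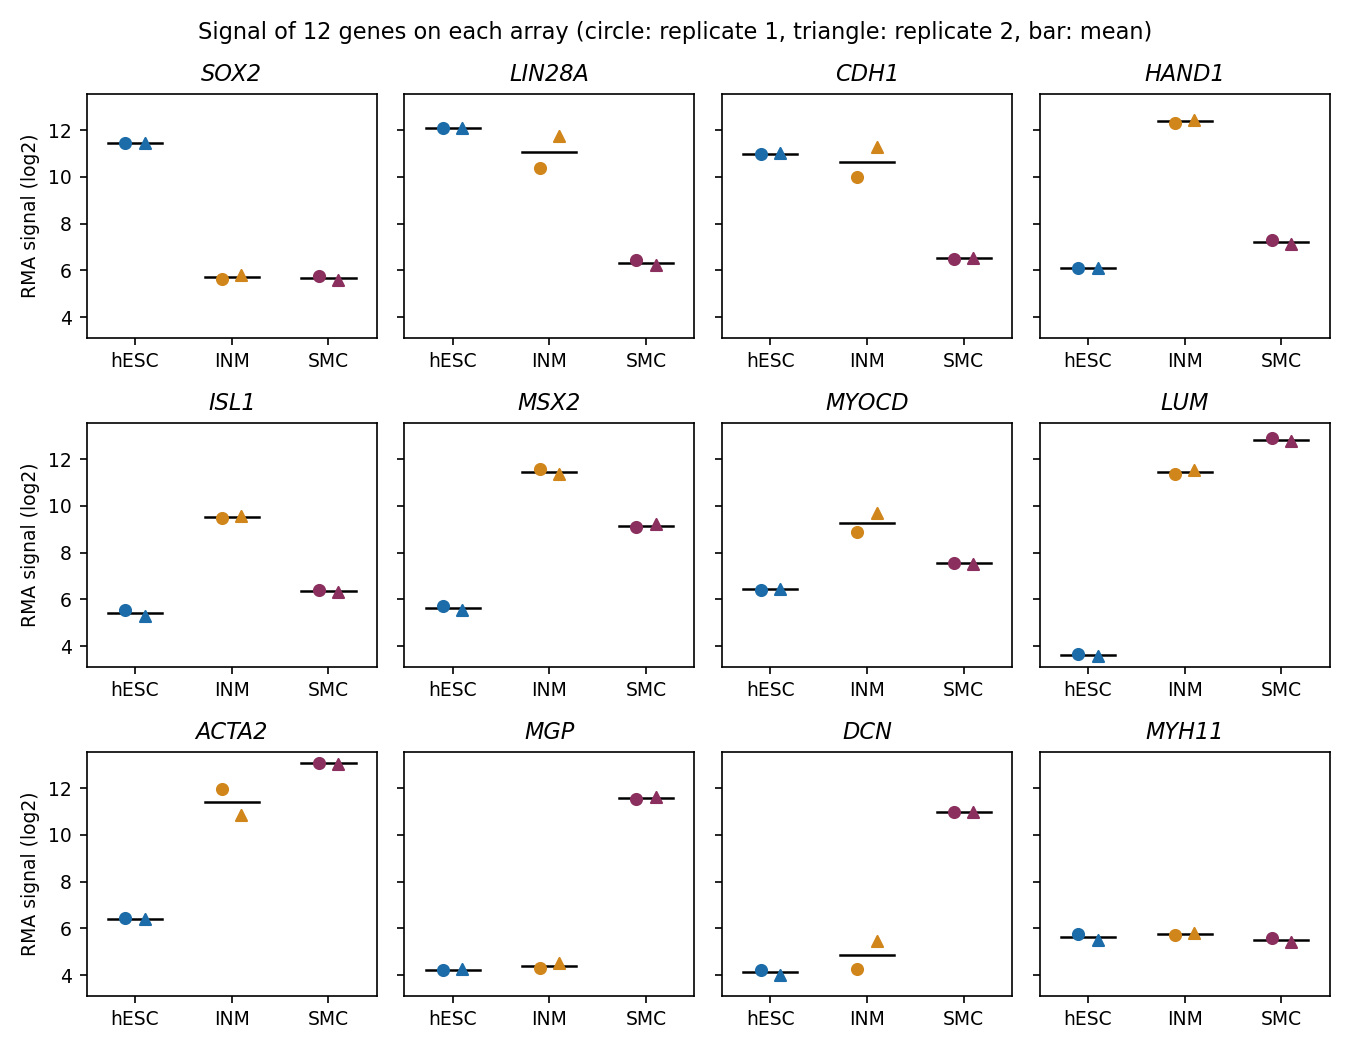
RMA signal (log2) of named genes on each array, with the group on the horizontal axis, circles for replicate 1, triangles for replicate 2 and a bar for the mean. SOX2 fell from 11.45 ± 0.02 in hESC to 5.72 ± 0.13 in INM, HAND1 was highest in INM at 12.37 ± 0.06, ACTA2 reached 13.06 ± 0.04 in SMC, and MYH11 stayed between means of 5.51 and 5.76 (SD, n = 2).

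The comparison of SMC with INM asks what changed between day 4 and day 21. MGP, an inhibitor of calcification in vessel walls and cartilage (probe set 7961514), rose from 4.41 ± 0.16 in INM to 11.56 ± 0.05 in SMC (SD, n = 2), with a log2 change of 7.15 (SE 0.12, adjusted p = 7.7e-06). Decorin (DCN), a proteoglycan that binds collagen fibres, rose by 6.11 (SE 0.35) on the log2 scale, and the enteric smooth muscle actin ACTG2 rose 15-fold. HAND1 fell back 35.3-fold to 7.23 ± 0.12, ISL1 fell 8.84-fold to 6.36 ± 0.07 and CDH1 fell 17.2-fold to 6.53 ± 0.03 (SD, n = 2). LIN28A, an RNA-binding protein that blocks maturation of let-7, fell by 26.6-fold, with a log2 change of -4.74 (SE 0.40, adjusted p = 6.6e-04).

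Other large rises were those of complement C7 (5.90, SE 0.23), the cytokine gene IL33 (5.15, SE 0.17), the pentraxin gene PTX3 (5.04, SE 0.12), EGFL6 (4.93, SE 0.14), the microfibril gene MFAP4 (4.79, SE 0.87) and AADAC (4.46, SE 0.28). Other large falls were those of FREM2 (-5.85, SE 0.20), the actin-bundling gene LCP1 (-4.91, SE 0.11), PRTG (-4.89, SE 0.31), the prostaglandin transporter gene SLCO2A1 (-4.89, SE 0.15), RASGRP1 (-4.45, SE 0.17) and PROM1 (-4.41, SE 0.20). MFAP4 stood at 7.80 ± 2.19 in INM (SD, n = 2). SOX2 was not called in this step, at -0.03 (SE 0.12, adjusted p = 0.877). ACTA2 rose further, by 1.65 (SE 0.33), vimentin (VIM) by 0.85 (SE 0.22) and PDGFRA by 1.71 (SE 0.42), while MYOCD fell, at -1.74 (SE 0.24). TAGLN, CNN1, GATA4 and MYH11 were not called, at 0.92, 0.46, 1.17 and -0.25 (adjusted p = 0.103, 0.0984, 0.123 and 0.247). KDR changed by 0.01 (SE 0.67, adjusted p = 0.991), and it was called lower without INM replicate 1, at -1.18, and higher without INM replicate 2, at 1.204. Without INM replicate 2 the change of ACTA2 was 1.09 and that of VIM 0.50, and without INM replicate 1 that of PDGFRA was 0.97. Leaving out 1 array ended some calls: ACTA2 was at 1.62 without SMC replicate 1. Without SMC replicate 2, MFAP4 was at 4.70, VIM at 0.84, PDGFRA at 1.69 and MYOCD at -1.72.

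Epithelial genes fell between day 4 and day 21. Of these, 0 of 19 measured genes rose, 15 fell and 4 did neither (0 and 19 adjusted over the list alone). Examples were the adhesion gene EPCAM at -3.76, GRHL2 at -3.24 and the claudin CLDN6 at -3.23. The epithelial list had a median change of -1.81 (camera adjusted p = 1.3e-11, adjusted p = 0.181 with an estimated correlation). Extracellular matrix genes rose further: 18 of 28 measured genes rose, 1 fell (FBLN1) and 9 did neither (19 and 1 adjusted over the list alone). Examples were LOX, a cross-linking enzyme of collagen and elastin, at 4.02 and FBLN5 at 2.95. The matrix list had a median change of 1.11 (camera adjusted p = 3.4e-10, adjusted p = 0.181 with an estimated correlation). In the pluripotency list 0 of 21 measured genes rose, 8 fell and 13 did neither (0 and 12 adjusted over the list alone). Examples were ZFP42 at -3.14 and LIN28B at -2.87. The pluripotency list had a median change of -0.65 (camera adjusted p = 6.1e-06, adjusted p = 0.181 with an estimated correlation). Among contractile genes 5 of 21 measured genes rose (ACTA2, ACTG2, DES, LMOD1 and TPM2), 1 fell (SYNPO2) and 15 did neither (5 and 1 adjusted over the list alone). The contractile list had a median change of 0.34 (camera adjusted p = 0.0408, adjusted p = 0.358 with an estimated correlation). This call was lost without INM replicate 2 (median 0.20) or SMC replicate 2 (median 0.31). Among epicardial and fibroblast markers 7 of 15 measured genes rose, 2 fell (BNC1 and KRT19) and 6 did neither (7 and 2 adjusted over the list alone). Examples were the protease gene FAP at 3.86 and THY1 at 2.43. The epicardial and fibroblast list had a median change of 0.71 (camera adjusted p = 0.00434, adjusted p = 0.181 with an estimated correlation). Among endothelial markers 4 of 16 measured genes rose (EMCN, ERG, FLT1 and PECAM1), 0 fell and 12 did neither (4 and 0 adjusted over the list alone). The endothelial list had a median change of 0.21 (camera adjusted p = 0.00492, adjusted p = 0.273 with an estimated correlation). The pluripotency median was -0.41 without INM replicate 2 and -0.34 without SMC replicate 1, and the epicardial and fibroblast median was 0.39 and 1.16 without INM replicates 1 and 2. The calls kept with any 1 array left out were those of 9 of 15 epithelial falls, 8 of 18 matrix rises and 5 of 7 epicardial rises. Calls of these genes ended: without SMC replicate 1 the adjusted p lay between 0.0504 and 0.205 for FBLN1, ACTA2, SYNPO2, BNC1, FLT1 and PECAM1, and without SMC replicate 2 it was 0.225 for DES.

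The target lists of both supplied signals were lower at day 21 than at day 4. In the BMP list 0 of 16 measured genes rose, 11 fell and 5 did neither (0 and 12 adjusted over the list alone). Examples were DLX5 at -3.66, GATA3 at -2.69 and MSX2 at -2.32. The BMP target list had a median change of -1.32 (camera adjusted p = 3.8e-07, adjusted p = 0.181 with an estimated correlation). Among Wnt targets 0 of 14 measured genes rose, 5 fell (AXIN2, NKD1, NOTUM, RNF43 and ZNRF3) and 9 did neither (0 and 5 adjusted over the list alone). The Wnt target list had a median change of -0.47 (camera adjusted p = 0.00561, adjusted p = 0.181 with an estimated correlation), with RNF43 at -2.65 and NKD1 at -1.58. AXIN2 and ZNRF3 had not been called at day 4, and APCDD1, DKK1 and LEF1, which had risen by then, were not called in this step. Among trophoblast and amnion markers 0 of 18 measured genes rose, 6 fell and 12 did neither (0 and 7 adjusted over the list alone). An example was VTCN1 at -3.34. The trophoblast and amnion list had a median change of -0.65 (camera adjusted p = 8.4e-04, adjusted p = 0.299 with an estimated correlation), and of -0.21 without INM replicate 1. Among neural crest markers 0 of 11 measured genes rose, 7 fell and 4 did neither (0 and 8 adjusted over the list alone). An example was the endothelin receptor EDNRB at -3.73. The neural crest list had a median change of -0.77 (camera adjusted p = 2.0e-04, adjusted p = 0.181 with an estimated correlation). In the MHC class I list 5 of 7 measured genes rose (B2M, PSMB8, TAP1, TAP2 and TAPBP), 0 fell and 2 did neither (5 and 0 adjusted over the list alone). The MHC class I list had a median change of 0.77 (camera adjusted p = 6.3e-05, adjusted p = 0.181 with an estimated correlation). Among ribosomal protein genes 5 of 62 measured genes rose (RPL22, RPL23, RPL27A, RPL37A and RPS21), 0 fell and 57 did neither (0 and 0 adjusted over the list alone). The ribosomal protein list had a median change of 0.10 (camera adjusted p = 0.0392, adjusted p = 0.575 with an estimated correlation), lost without INM replicate 1 (adjusted p = 0.132) or SMC replicate 2 (adjusted p = 0.0636). Calls were kept in all 6 fits with 1 array left out for 6 of 11 BMP falls, 4 of 6 trophoblast falls and 4 of 7 neural crest falls. Some calls ended in such fits: without SMC replicate 1 those of AXIN2, TAP2, RPL23, RPL37A and RPS21. Without SMC replicate 2 those of NOTUM, PSMB8, RPL22 and RPL27A ended.

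At the preset correlation the DNA replication and mitosis lists were called lower in SMC than in INM. In the DNA replication list 0 of 24 measured genes rose, 10 fell and 14 did neither (0 and 13 adjusted over the list alone). An example was the helicase subunit MCM7 at -1.35 (SE 0.18). The DNA replication list had a median change of -0.72 (camera adjusted p = 1.0e-05, adjusted p = 0.622 with an estimated correlation), and of -0.35 without INM replicate 2 (adjusted p = 0.00112), the array in which all 24 genes were the higher of the INM pair. In the mitosis list 0 of 20 measured genes rose, 1 fell (CENPF) and 19 did neither (0 and 0 adjusted over the list alone). The mitosis list had a median change of -0.68 (camera adjusted p = 0.00339, adjusted p = 0.675 with an estimated correlation), and the call was lost without INM replicate 2 (median -0.09, adjusted p = 0.38), where all 20 genes were the higher too. The median was -1.30 without INM replicate 1. Among polycomb and DNA methylation genes 0 of 19 measured genes rose, 10 fell and 9 did neither (2 and 12 adjusted over the list alone). Examples were DNMT3B at -2.26 (SE 0.17) and JARID2 at -1.57 (SE 0.11). The polycomb and DNA methylation list had a median change of -0.45 (camera adjusted p = 0.00340, adjusted p = 0.181 with an estimated correlation). For chromatin remodelling genes 1 of 49 measured genes rose (SMARCD3), 14 fell and 34 did neither (1 and 15 adjusted over the list alone). Examples were CHD7 at -1.65 (SE 0.15) and ARID2 at -1.46 (SE 0.11). The remodelling list had a median change of -0.20 (camera adjusted p = 0.00340, adjusted p = 0.622 with an estimated correlation), lost without INM replicate 2 (adjusted p = 0.0528). For histone chaperones 0 of 22 measured genes rose, 4 fell (CHAF1A, CHAF1B, RBBP4 and SET) and 18 did neither (0 and 4 adjusted over the list alone). The chaperone list had a median change of -0.34 (camera adjusted p = 0.0416, adjusted p = 0.675 with an estimated correlation), lost without INM replicate 2 (adjusted p = 0.463) or SMC replicate 2 (adjusted p = 0.147), with the low-signal filter (adjusted p = 0.0917) and with the mean of probe sets (adjusted p = 0.0565). Without INM replicates 1 and 2 the remodelling median was -0.35 and -0.12, and the chaperone median -0.54 and -0.16. Replication-dependent histone genes had no list call, and 4 of 57 measured genes rose (H2BC12, H2BC26, H4C5 and H4C8), 3 fell (H3C7, H4C3 and H4C4) and 50 did neither (2 and 3 adjusted over the list alone), but the list was called higher, at 0.27, without INM replicate 2 (adjusted p = 7.8e-04). In the histone variant list 1 of 8 measured genes rose (H2AJ), 2 fell (MACROH2A1 and MACROH2A2) and 5 did neither (1 and 3 adjusted over the list alone). In all 6 fits with 1 array left out, calls were kept for 1 of 10 DNA replication falls, 2 of 10 polycomb falls and 2 of 14 remodelling falls. Calls of these genes ended: without SMC replicate 1 the adjusted p was 0.220 for CHAF1A, 0.113 for H4C5, 0.111 for H4C8, 0.148 for H4C3 and 0.183 for H2AJ, and without SMC replicate 2 it lay between 0.0571 and 0.249 for CENPF, SMARCD3, CHAF1B, RBBP4, SET, H2BC12, H2BC26, H3C7, H4C4 and MACROH2A1.

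No call was made for the remaining lists, with camera adjusted p between 0.0693 and 0.969. In the lateral and cardiac mesoderm list 2 of 24 measured genes rose (PDGFRA and TBX20), 7 fell and 15 did neither (3 and 7 adjusted over the list alone). In the primitive streak list 0 of 18 measured genes rose, 3 fell (EVX1, MIXL1 and WNT3) and 15 did neither (0 and 2 adjusted over the list alone). In the paraxial and intermediate mesoderm list 0 of 17 measured genes rose, 1 fell (PAX3) and 16 did neither (0 and 1 adjusted over the list alone). Among smooth muscle regulators 0 of 15 measured genes rose, 2 fell (HEY2 and MYOCD) and 13 did neither (0 and 2 adjusted over the list alone). Among genes of mesenchymal transition 4 of 16 measured genes rose (CDH2, THY1, VIM and ZEB1), 1 fell (SNAI1) and 11 did neither (5 and 1 adjusted over the list alone). Among endoderm markers 1 of 14 measured genes rose (CXCR4), 1 fell (APOA2) and 12 did neither (1 and 1 adjusted over the list alone). Among neuroectoderm markers 0 of 16 measured genes rose, 2 fell (MAP2 and NES) and 14 did neither (0 and 2 adjusted over the list alone). Among haematopoietic markers 1 of 13 measured genes rose (CD34), 1 fell (CSF1R) and 11 did neither (0 and 0 adjusted over the list alone). Among cardiomyocyte markers 1 of 14 measured genes rose (PLN), 2 fell (MYL7 and TNNC1) and 11 did neither (1 and 2 adjusted over the list alone). Among skeletal muscle markers 0 of 12 measured genes rose, 1 fell (ACTA1) and 11 did neither (0 and 0 adjusted over the list alone). In the HOX list 5 of 27 measured genes rose (HOXB13, HOXB7, HOXB9, HOXC9 and HOXD10), 1 fell (HOXB2) and 21 did neither (5 and 1 adjusted over the list alone). In the YAP list 1 of 13 measured genes rose (NT5E), 2 fell (AMOTL2 and ANKRD1) and 10 did neither (1 and 2 adjusted over the list alone). In the glycolysis list 3 of 16 measured genes rose (ALDOC, GPI and HK2), 3 fell (HK1, SLC2A1 and SLC2A3) and 10 did neither (4 and 4 adjusted over the list alone). For oxidative phosphorylation 5 of 75 measured genes rose (ATP5F1D, COX6B1, NDUFA11, NDUFB11 and UQCRQ), 1 fell (ATP5PB) and 69 did neither (2 and 0 adjusted over the list alone). For p53 targets 3 of 12 measured genes rose (CDKN1A, SESN2 and TNFRSF10B), 0 fell and 9 did neither (3 and 0 adjusted over the list alone). Lists called in their direction with an array left out were lateral mesoderm, primitive streak and mesenchymal transition without INM replicate 1 (adjusted p = 0.0339, 0.0278 and 0.00456), and neuroectoderm, HOX and oxidative phosphorylation without INM replicate 2 (adjusted p = 0.0358, 0.0433 and 0.0433). Mesenchymal transition was also called with the mean of probe sets (adjusted p = 0.0307). The medians of the paraxial mesoderm and oxidative phosphorylation lists changed sign under another scaling. Median and mean had opposite signs for endoderm (-0.16 and 0.03) and glycolysis (0.06 and -0.04), and for haematopoietic markers camera pointed up against a median of -0.01. The calls kept with any 1 array left out were those of 4 of 7 lateral mesoderm falls. Calls of these members ended: without SMC replicate 1 the adjusted p lay between 0.0576 and 0.231 for EVX1, CDH2, ZEB1, NES, CSF1R, MYL7, TNNC1, ACTA1, HOXB7, HOXB2, AMOTL2, SLC2A1, ATP5PB and TNFRSF10B, and without SMC replicate 2 it lay between 0.0510 and 0.263 for PDGFRA, TBX20, WNT3, PAX3, HEY2, MYOCD, VIM, CD34, HOXC9, NT5E, GPI, HK2, HK1, ATP5F1D, COX6B1, NDUFA11, NDUFB11, UQCRQ, CDKN1A and SESN2.

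Between INM and SMC 3874 genes (21.0%) were called, of which 1831 were higher and 2043 lower in SMC. At least 2-fold changes numbered 670 up and 704 down, and at least 8-fold changes 61 and 44. Groups did not overlap in 62.0% of genes, where chance gives 33.3%. The count was 2541 without hESC replicate 1, 2541 without hESC replicate 2, 6143 without INM replicate 1, 1192 without SMC replicate 1 and 1134 without SMC replicate 2, and it was 2541 when the 4 arrays compared were fitted alone. The share of calls that were higher was 47.3%, and with all probe sets tested singly 3002 were higher and 2053 lower.

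The comparison of SMC with hESC spans the whole course. LUM rose from 3.63 ± 0.03 to 12.84 ± 0.09 (SD, n = 2), with a log2 change of 9.21 (SE 0.12, adjusted p = 1.1e-06). ACTA2 rose 99.5-fold, from 6.42 ± 0.02 to 13.06 ± 0.04 (SD, n = 2), with a log2 change of 6.64 (SE 0.33, adjusted p = 4.0e-05), and LOX rose 116-fold. PTPRZ1, a receptor phosphatase, fell from 11.10 ± 0.04 to 4.14 ± 0.27 (SD, n = 2), with a log2 change of -6.96 (SE 0.30, adjusted p = 2.6e-05). The pluripotency genes SOX2 and LIN28A fell by 54.4-fold and 53.8-fold, and CRIPTO fell, at -6.53 (SE 0.29). MYH11 was not called, at -0.13 (SE 0.14, adjusted p = 0.507).

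The other large rises were MGP (7.32, SE 0.12), DCN (6.85, SE 0.35), SRPX2 (6.36, SE 0.26), DKK1 (6.35, SE 0.53) and TDO2, an enzyme of tryptophan breakdown (6.30, SE 0.24). The other large falls were IDO1 (-5.93, SE 0.14), the Wnt modulator SFRP2 (-5.70, SE 0.28), PROM1 (-5.69, SE 0.20) and USP44 (-5.37, SE 0.16). CNN1 rose by 1.94 (SE 0.16), TAGLN by 1.58 (SE 0.33), VIM by 2.41 (SE 0.22), PDGFRA by 3.58 (SE 0.42) and GATA4 by 3.19 (SE 0.45). HAND1, ISL1 and MYOCD were above hESC, at 1.13 (SE 0.12), 0.95 (SE 0.13) and 1.11 (SE 0.24), while CDH1 fell, at -4.46 (SE 0.38). EOMES and KDR were not called, at 0.09 and 0.01 (adjusted p = 0.664 and 0.994). The following calls were lost with 1 array left out: without SMC replicate 2 the adjusted p was 0.0773 for TAGLN, and without hESC replicate 1 it was 0.0798 for MYOCD.

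In the extracellular matrix list 26 of 28 measured genes rose, 0 fell and 2 did neither (27 and 1 adjusted over the list alone). The matrix list had a median change of 3.37 (camera adjusted p = 9.7e-17, adjusted p = 0.148 with an estimated correlation). For pluripotency genes 0 of 21 measured genes rose, 20 fell and 1 did neither (0 and 20 adjusted over the list alone). An example was L1TD1 at -5.05. The pluripotency list had a median change of -2.98 (camera adjusted p = 6.7e-13, adjusted p = 0.148 with an estimated correlation). Among contractile genes 15 of 21 measured genes rose, 0 fell and 6 did neither (17 and 0 adjusted over the list alone). Examples were ACTG2 at 2.58, the integrin ITGA8 at 3.42 and CSRP1 at 2.65. The contractile list had a median change of 0.87 (camera adjusted p = 1.8e-06, adjusted p = 0.162 with an estimated correlation). Among their regulators 6 of 15 measured genes rose, 0 fell and 9 did neither (6 and 0 adjusted over the list alone). Examples were PRRX1 at 4.62 and TCF21 at 2.30. The smooth muscle regulator list had a median change of 0.45 (camera adjusted p = 0.0205, adjusted p = 0.303 with an estimated correlation), lost with the low-signal filter (adjusted p = 0.0607). Among lateral and cardiac mesoderm genes 14 of 24 measured genes rose, 1 fell (FOXH1) and 9 did neither (15 and 1 adjusted over the list alone). Examples were TBX20 at 5.62 and HAND2 at 3.49. The lateral mesoderm list had a median change of 1.16 (camera adjusted p = 2.8e-05, adjusted p = 0.433 with an estimated correlation). Of the genes of mesenchymal transition, 12 of 16 measured genes rose, 0 fell and 4 did neither (13 and 0 adjusted over the list alone). Examples were TGFBI at 5.97 and SNAI2 at 5.79. The mesenchymal transition list had a median change of 2.70 (camera adjusted p = 6.3e-08, adjusted p = 0.318 with an estimated correlation). Among epicardial and fibroblast markers 12 of 15 measured genes rose, 0 fell and 3 did neither (12 and 0 adjusted over the list alone). An example was FAP at 4.26. The epicardial and fibroblast list had a median change of 1.86 (camera adjusted p = 3.9e-06, adjusted p = 0.148 with an estimated correlation). Among epithelial genes 2 of 19 measured genes rose (KRT18 and KRT8), 15 fell and 2 did neither (2 and 16 adjusted over the list alone). Examples were EPCAM at -4.54 and CLDN7 at -4.01. The epithelial list had a median change of -2.21 (camera adjusted p = 1.8e-06, adjusted p = 0.200 with an estimated correlation). Calls were kept in all 6 fits with 1 array left out for 24 of 26 matrix rises, 17 of 20 pluripotency falls, 10 of 15 contractile rises and 2 of 6 regulator rises. The same held for 10 of 14 lateral mesoderm rises, 11 of 12 mesenchymal transition rises, 9 of 12 epicardial rises and 12 of 15 epithelial falls.

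Endothelial markers rose as a list: 6 of 16 measured genes rose, 0 fell and 10 did neither (6 and 0 adjusted over the list alone). Examples were ERG at 2.04, PECAM1 at 1.43 and EMCN at 1.19. The endothelial list had a median change of 0.35 (camera adjusted p = 0.00909, adjusted p = 0.328 with an estimated correlation). In the HOX list 12 of 27 measured genes rose, 0 fell and 15 did neither (12 and 0 adjusted over the list alone). Examples were HOXD10 at 3.59 and HOXB9 at 3.56. The HOX list had a median change of 0.37 (camera adjusted p = 0.00110, adjusted p = 0.494 with an estimated correlation). Among BMP targets 12 of 16 measured genes rose, 1 fell (ID1) and 3 did neither (13 and 1 adjusted over the list alone). An example was BAMBI at 3.30. The BMP target list had a median change of 0.90 (camera adjusted p = 9.6e-06, adjusted p = 0.200 with an estimated correlation). Among YAP targets 8 of 13 measured genes rose, 0 fell and 5 did neither (10 and 0 adjusted over the list alone). Examples were NT5E at 4.35 and TGFB2 at 4.02. The YAP target list had a median change of 0.87 (camera adjusted p = 1.4e-04, adjusted p = 0.433 with an estimated correlation). Among DNA replication genes 1 of 24 measured genes rose (CCNE2), 15 fell and 8 did neither (1 and 19 adjusted over the list alone). Examples were ORC1 at -2.01 and MCM6 at -1.89. The DNA replication list had a median change of -1.0 (camera adjusted p = 2.8e-05, adjusted p = 0.676 with an estimated correlation). For mitosis genes 0 of 20 measured genes rose, 6 fell and 14 did neither (0 and 5 adjusted over the list alone). An example was CENPF at -1.68. The mitosis list had a median change of -0.89 (camera adjusted p = 7.6e-04, adjusted p = 0.707 with an estimated correlation). In all 6 fits with 1 array left out, calls were kept for 4 of 6 endothelial rises, 6 of 12 HOX rises, 9 of 12 BMP rises and 5 of 8 YAP rises. The same held for 7 of 15 DNA replication falls and 1 of 6 mitosis falls. Calls of CCNE2 and ID1 ended as well: without hESC replicate 1 at 0.54 for CCNE2, and without hESC replicate 2 at -0.57 for ID1.

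Chromatin genes changed in several lists. Among replication-dependent histones 1 of 57 measured genes rose (H2BC12), 19 fell and 37 did neither (1 and 19 adjusted over the list alone). Examples were H1-1 at -2.41 and H2BC14 at -1.81. The histone list had a median change of -0.47 (camera adjusted p = 3.0e-05, adjusted p = 0.676 with an estimated correlation), and unnamed probe sets and small nucleolar RNA genes had medians of -0.17 and -0.63. For histone chaperones 0 of 22 measured genes rose, 11 fell and 11 did neither (0 and 13 adjusted over the list alone). An example was NASP at -1.86. The chaperone list had a median change of -0.50 (camera adjusted p = 2.4e-04, adjusted p = 0.675 with an estimated correlation). Among polycomb and DNA methylation genes 3 of 19 measured genes rose (PHC2, TET2 and TET3), 9 fell and 7 did neither (3 and 12 adjusted over the list alone). Examples were DNMT3B at -4.88 and JARID2 at -2.61. The polycomb and DNA methylation list had a median change of -0.54 (camera adjusted p = 0.00292, adjusted p = 0.230 with an estimated correlation). Chromatin remodelling genes had no list call: 6 of 49 measured genes rose, 12 fell and 31 did neither (6 and 12 adjusted over the list alone), with CHD3 at 1.31 and BRD7 at -1.05. In the histone variant list 3 of 8 measured genes rose (H2AJ, MACROH2A1 and MACROH2A2), 0 fell and 5 did neither (3 and 0 adjusted over the list alone), with a median of -0.01, which became 0.13 with median centring, and a mean of 0.24. The calls kept with any 1 array left out were those of 8 of 19 histone falls, 3 of 11 chaperone falls, 6 of 9 polycomb falls and 4 of 6 remodelling rises. The same held for 4 of 12 remodelling falls. Members named above that lost their call were H2AJ without SMC replicate 1, at 0.39, and PHC2 and TET3 without SMC replicate 2, at 0.93 and 0.57.

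Camera adjusted p lay between 0.193 and 0.954 for the remaining lists, which were not called. Among Wnt targets 5 of 14 measured genes rose (APCDD1, DKK1, LEF1, LGR5 and TNFRSF19), 2 fell (RNF43 and ZNRF3) and 7 did neither (5 and 2 adjusted over the list alone), with a median of -0.10 and a mean of 1.19. Among neural crest markers 4 of 11 measured genes rose (MSX1, MSX2, SNAI2 and SOX9), 1 fell (EDNRB) and 6 did neither (4 and 2 adjusted over the list alone), with a median of -0.22 and a mean of 0.58. Among MHC class I genes 2 of 7 measured genes rose (B2M and TAPBP), 0 fell and 5 did neither (2 and 0 adjusted over the list alone), with a median of -0.06 and a mean of 0.49. In the primitive streak list 0 of 18 measured genes rose, 4 fell (MESP1, MIXL1, NODAL and TBXT) and 14 did neither (0 and 1 adjusted over the list alone). In the paraxial and intermediate mesoderm list 1 of 17 measured genes rose (OSR1), 1 fell (DLL3) and 15 did neither (0 and 1 adjusted over the list alone). In the trophoblast and amnion list 3 of 18 measured genes rose (GATA2, GATA3 and TFAP2A), 1 fell (TFAP2C) and 14 did neither (3 and 1 adjusted over the list alone). In the endoderm list 1 of 14 measured genes rose (CXCR4), 1 fell (FOXA3) and 12 did neither (1 and 1 adjusted over the list alone). In the neuroectoderm list 0 of 16 measured genes rose, 1 fell (OTX2) and 15 did neither (0 and 1 adjusted over the list alone). In the haematopoietic list 2 of 13 measured genes rose (CD34 and RUNX1), 1 fell (HBE1) and 10 did neither (0 and 0 adjusted over the list alone). In the cardiomyocyte list 1 of 14 measured genes rose (PLN), 3 fell (RYR2, TNNI3 and TTN) and 10 did neither (1 and 3 adjusted over the list alone). In the skeletal muscle list 1 of 12 measured genes rose (DMD), 4 fell (ACTA1, MYF6, MYH2 and TNNT1) and 7 did neither (1 and 4 adjusted over the list alone). For glycolysis 5 of 16 measured genes rose (ALDOA, ALDOC, PFKL, PFKP and PKM), 3 fell (LDHB, SLC2A1 and SLC2A3) and 8 did neither (5 and 4 adjusted over the list alone). For oxidative phosphorylation 9 of 75 measured genes rose, 6 fell and 60 did neither (2 and 1 adjusted over the list alone). For p53 targets 4 of 12 measured genes rose (CDKN1A, SESN2, TNFRSF10B and ZMAT3), 1 fell (RRM2B) and 7 did neither (5 and 1 adjusted over the list alone). For ribosomal proteins 2 of 62 measured genes rose (RPL26L1 and RPS23), 3 fell (RPL23, RPL39L and RPS24) and 57 did neither (1 and 0 adjusted over the list alone). The median changed sign under another scaling for all of these lists except the neural crest, primitive streak, glycolysis, oxidative phosphorylation and p53 lists. Median and mean also had opposite signs for the trophoblast, endoderm and haematopoietic lists. Calls were kept in all 6 fits with 1 array left out for 1 of 9 oxidative phosphorylation rises and 1 of 6 oxidative phosphorylation falls. Calls of these members also ended: without SMC replicate 1 the adjusted p lay between 0.0506 and 0.192 for MIXL1, NODAL, TBXT, DLL3, HBE1, TNNI3, MYH2 and RPS24, and without SMC replicate 2 it lay between 0.0510 and 0.222 for LGR5, RNF43, MESP1, OSR1, RUNX1, MYF6, ALDOA, ALDOC, PFKL, PFKP, PKM, LDHB, CDKN1A, RPL26L1 and RPL23, and without hESC replicate 1 it was 0.116 for TNFRSF19 and 0.197 for TNNT1, and without hESC replicate 2 it was 0.184 for SOX9, 0.207 for CD34, 0.137 for DMD and 0.168 for RPL39L.

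**Figure D3:**
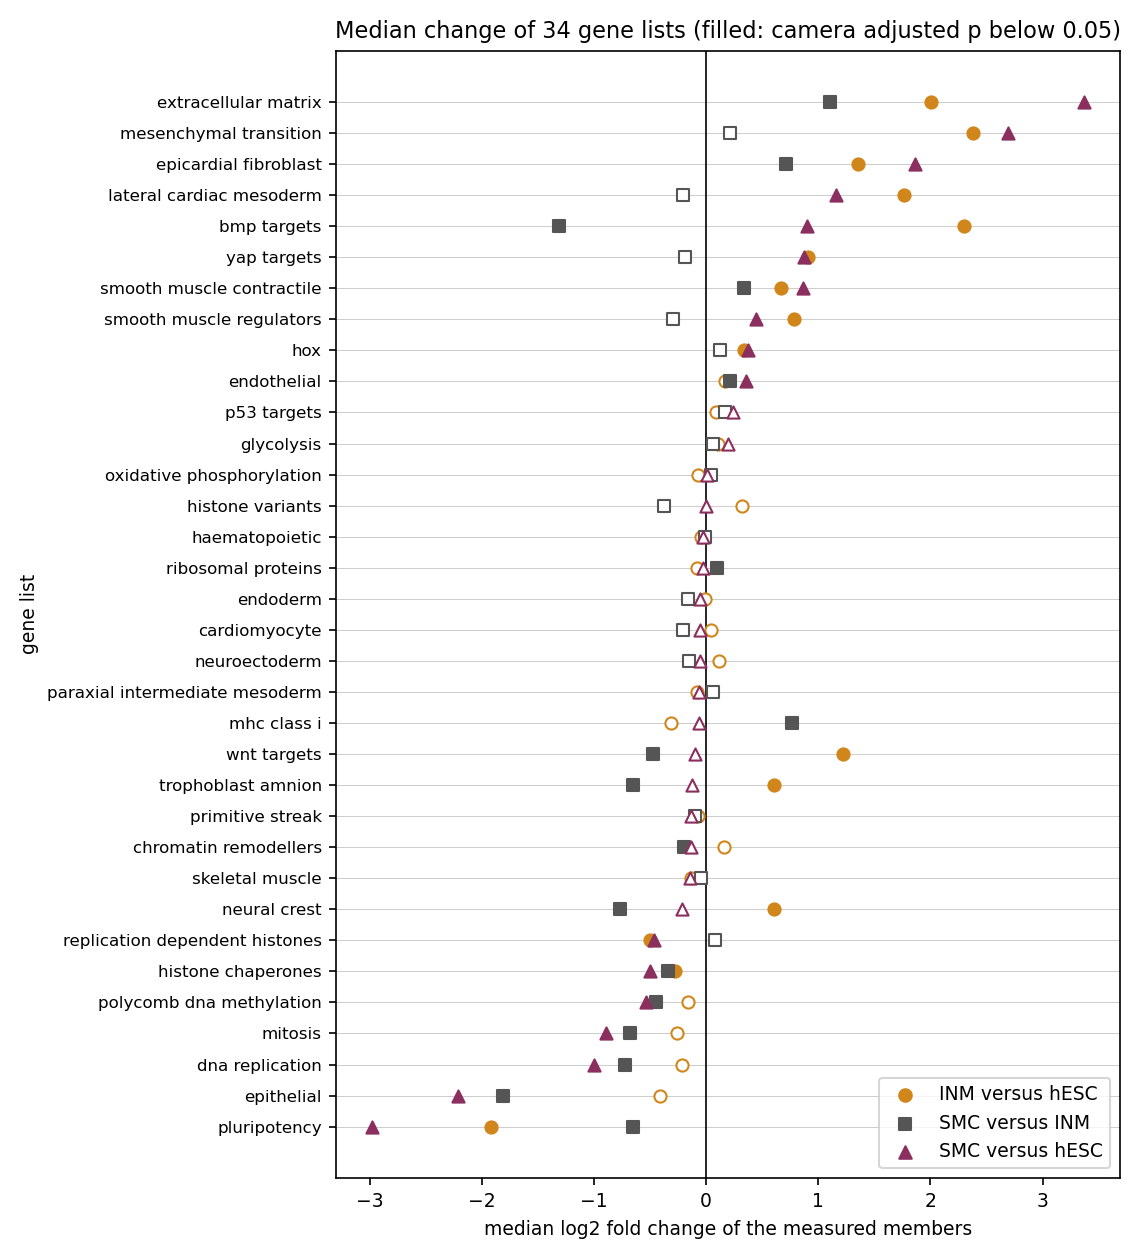
Median log2 change of the measured members of each of the 34 gene lists (vertical axis) in the 3 comparisons, with filled symbols where the camera adjusted p was below 0.05. Between SMC and hESC the extracellular matrix list reached 3.37 and the pluripotency list -2.98, and the BMP target list stood at 2.30 in INM versus hESC and -1.32 in SMC versus INM.

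Between hESC and SMC 6859 genes (37.2%) were called, of which 3625 were higher and 3234 lower in SMC. At least 2-fold changes numbered 1631 up and 1128 down, and at least 8-fold changes 229 and 103. Groups did not overlap in 75.3% of genes, where chance gives 33.3%. The share of calls that were higher was 52.9%, against 66.5% with median centring, which moved the all-gene median by 0.13. All probe sets tested singly gave 4044 higher and 5428 lower. The arrays compared, fitted alone, gave 9200 calls. Without hESC replicate 1 or 2 and SMC replicate 1 or 2 the count was 4134, 4329, 3982 and 3803. The F test called 8379 genes (45.5%) as different between any groups, and 4847, 5093, 5047 and 4968 without the same arrays.

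The steps were then set against each other, gene by gene. HAND1 and MSX2 are examples of genes that rose and then fell, and LUM of a gene that rose in both steps, at 11.46 ± 0.11 in INM and 12.84 ± 0.09 in SMC (SD, n = 2). Both steps called 2068 genes, of which 409 rose in both (347 expected of independent lists), 254 fell in both (303), 903 rose and then fell (387) and 502 fell and then rose (272). Simulated unchanged groups that share the INM arrays gave a mean of 0.05 genes called in both steps, a value for the case of no change in any gene, in which hardly any gene is called. The correlation of the steps' changes across genes was -0.17, against -0.50 in the simulations, and the covariance was -0.08, against -0.02 in the simulations and -0.05 from the spread of the INM pair itself. With INM replicate 1 in the first step and replicate 2 in the second, 49.9% of the genes called in both steps turned, and 64.0% with the arrays exchanged, where independent lists give 50.5% and 50.3%. Part of the excess of turning genes may come from the shared INM arrays. Without hESC replicates 1 and 2, INM replicates 1 and 2 and SMC replicates 1 and 2 in turn, both steps called 933, 973, 3579, 3138, 616 and 614 genes.

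Both derivatives differed from hESC in 4177 shared genes, of which 2238 were higher in both (686 expected of independent lists), 1746 lower in both (480), 102 higher in INM and lower in SMC (612) and 91 the reverse (538). SOX2 and CRIPTO were lower in both, and ACTA2 and LUM higher in both. Simulated unchanged groups sharing the hESC arrays gave 0 shared calls, again a value for no change in any gene. Across genes the correlation was 0.72, against 0.50 simulated, and the covariance 0.50, against 0.02, and part of the excess may come from the shared hESC arrays. Of the 3625 genes higher in SMC than hESC, 2238 (61.7%) were already higher in INM and 746 (20.6%) were called in the second step alone. Of the 3234 lower genes, 1746 (54.0%) were already lower in INM and 638 (19.7%) were called in the second step alone. Without hESC replicate 1 or 2 and SMC replicate 1 or 2 the shared count was 2018, 2225, 2435 and 2391.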

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

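Of the tests in this part, the one on array scaling was fixed before its result was seen and the one on RNA preparation was chosen after. Probe sets without a gene name were not among the genes tested, and among the 12083 of them 531 were called higher and 3587 lower in INM than in hESC. Between SMC and hESC 504 were called higher and 2167 lower, and between SMC and INM 1295 and 362. Per array, their median signal on the log2 scale was 5.62 and 5.65 in hESC, 5.11 and 5.04 in INM, and 5.34 and 5.31 in SMC, while that of named probe sets lay between 7.09 and 7.12.

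Small nucleolar RNA genes, which guide chemical modification of ribosomal RNA, moved with the unnamed probe sets: 106 of 175 were called lower in INM than in hESC, with a median change of -0.76, or -0.60 with quantile normalization again and -0.58 with median centring. Array scaling or background would move other genes of the same level alike, and protein-coding genes drawn to match them had a median change of -0.054 (SD 0.032 over 10000 draws), which argues against it as the whole cause. RNA preparation that differed between the groups may lower short and unnamed transcripts together, and the unnamed probe sets had a median change of -0.30. That explanation cannot be told apart from the groups, because the arrays of a group moved together and nothing records preparation apart from them. The differentiation stage stays open as well and was not tested.

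Other RNA classes depended on the scaling. Of 173 microRNA genes 60 were called lower in INM than in hESC, and 31 with quantile normalization again and 34 with median centring. Of 632 long noncoding RNA genes 128 were called lower, against 74 and 68 under the same settings.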

How the results depend on the processing

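Crossed replicate numbers and protein-coding genes alone were added after the data were seen; every other setting of this part was planned. Of 547 named gene results 458 were called, 272 of them also in each fit with 1 array left out. No called gene could reverse in a fit with 1 array left out, since its groups did not overlap. With 1 array left out, counts ranged from 2939 to 7520 in INM versus hESC, from 1134 to 6143 in SMC versus INM, from 3803 to 9200 in SMC versus hESC, from 4847 to 10774 for the F test, from 614 to 3579 for both steps and from 2018 to 5760 for both derivatives. Fits that lose an hESC or SMC array have fewer samples behind the spread, which then rests more on the INM pair. With only the arrays compared, calls were 4498 in INM versus hESC, 2541 in SMC versus INM and 9200 in SMC versus hESC. The shared spread gave 6217, 3874 and 6859. With all probe sets singly, INM versus hESC gave 10688 calls and the F test 12888, over 33297 probe sets instead of 18417 genes.

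A minimum of 2-fold left 2063 calls in INM versus hESC, 1374 in SMC versus INM, 2759 in SMC versus hESC, 511 for both steps and 1348 for both derivatives. Testing against a change of 0.58 (treat) left 1425, 775, 2211, 258 and 938. Both are stricter by construction. With an estimated correlation 0, 0 and 0 gene lists were called in the 3 comparisons, against 15, 17 and 17, and the cause was not tested. The low-signal filter, quantile normalization again, median centring, the variance trend, array weights and the mean of probe sets kept every total of called genes within 1.5 times its value, while genes called lower in INM than in hESC went from 2731 to 1589 with median centring. Among the named genes, 3 without a call were called in opposite directions by fits without INM replicate 1 and without INM replicate 2: KDR in INM versus hESC (1.18 and -1.196) and in SMC versus INM (-1.18 and 1.204), STMN2 in INM versus hESC (-0.61 and 2.26) and in SMC versus INM (2.17 and -0.70), and TEK in INM versus hESC (1.63 and -0.92). For these the INM arrays lay apart, and the cause was not tested.

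With the replicate number as a block, 5713, 3392 and 6429 genes were called in INM versus hESC, SMC versus INM and SMC versus hESC, 7711 by the F test, 1740 in both steps and 3808 in both derivatives, and the number of lists called stayed at 15, 17 and 17. Same-numbered arrays did not deviate together across genes (r = 0.07 for hESC with INM, -0.12 for hESC with SMC and -0.07 for INM with SMC), so that the number was not taken as a pairing. Crossed numbers, with a replicate block in SMC versus hESC, gave 6881 calls. Protein-coding genes alone gave 5781, 3763 and 6500 calls. How far signals lay over background is not given in the sources used here, and low signals have less room to fall.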

Other observations

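The genes of the next 2 paragraphs were chosen after their values were seen, and of the tests that follow those on undifferentiated cells, on chance values and on a single INM array were chosen after the result was seen. The tests on a single INM array and on chance values took the place of earlier ones that were void, the first because it ran on genes picked for the pattern and the second because unchanged groups give hardly any call.

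CXCL10, CXCL11, GBP2 and IFI6, each known to be induced by interferons, rose between INM and SMC, and no list of such genes was tested. CXCL10, a chemokine, stood at 2.89 ± 0.07 in INM and 6.72 ± 0.12 in SMC (SD, n = 2), a log2 change of 3.84 (SE 0.18, adjusted p = 9.9e-05), and CXCL11 rose by 3.0 (SE 0.15). GBP2, a guanylate-binding protein, rose by 3.58 (SE 0.20) and IFI6 by 2.10 (SE 0.11), while none of these 4 genes was called between INM and hESC, with changes of -0.35, -0.18, -0.04 and 0.25. The INM levels of CXCL10, CXCL11 and GBP2 and the INM levels of both MIR302 genes given next are not shown to lie above background.

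Among microRNA genes, MIR302A and MIR302B, members of a cluster active in pluripotent cells, fell between hESC and INM, with log2 changes of -6.60 (SE 0.24, adjusted p = 2.8e-05) and -7.30 (SE 0.47, adjusted p = 1.7e-04). MIR181B1 rose between INM and SMC, from 5.14 ± 0.73 to 8.97 ± 0.08 (SD, n = 2), a log2 change of 3.83 (SE 0.31, adjusted p = 6.0e-04). The pseudogene MTND2P28 fell by 14.7-fold in INM and rose by 12.1-fold in SMC, and its own level is uncertain because it is nearly identical to a mitochondrial gene. The calls of these microRNA genes, of the pseudogene and of the 4 genes above were kept in each fit with 1 array left out.

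The INM arrays differed in cell division genes: the 20 mitosis genes were all higher in replicate 2, with a median of -1.14 for replicate 1 minus replicate 2, and 315 genes were more than 1 on the log2 scale higher in replicate 1 and 385 in replicate 2. If array scaling were the whole cause, normalizing again would remove the difference, but the median was still -1.07 after quantile normalization again. Undifferentiated cells left in replicate 2 would have to supply 54.5% of its own mitosis signal. But of the 43 genes abundant in hESC and at least 8-fold lower in SMC the 10th percentile stood at 3.30% of the hESC level. The median stood at 23.4% and SOX2 at 2.00%. A difference in stage or growth between the INM samples may remain and was not tested, since the design names none within a group.

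Of the 2068 genes called in both steps 1405 turned at INM, rising and then falling or the reverse. Chance values of the shared INM arrays stay open as a source of their excess: with a different INM array in each step 49.9% of the genes called in both steps turned in one arrangement and 64.0% in the other, where independent lists give 50.5% and 50.3%. If 1 INM array alone made the pattern, genes that turned without it would lie elsewhere in it, but 83.3% of 2526 genes without replicate 1 and 82.7% of 2175 without replicate 2 lay, in the left-out array, beyond both other group means on the called side. The number of turning genes was 653 and 684 without hESC replicates 1 and 2, and 416 and 418 without SMC replicates 1 and 2. Expression that passes through a separate stage at INM may be another candidate explanation, which stays an untested hypothesis, and time in culture cannot be separated from stage here.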
